A study of Homo sapiens with 9 samples.

How the data were processed

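Total RNA of A2780, A2780cis and Hs578T cells, taken 72 hours after transfection with 40 nM siRNA (siLuc, siEPIC1_1 or siEPIC1_2), was sequenced as 9 libraries, 1 per line and siRNA. The deposited table holds expected counts per gene, not scaled to library size. The authors' processing notes name STAR, RSEM and GRCh38, without versions or the role of each, and the annotation release and strand setting are not stated. Of the deposited values 85.4% were whole numbers, and they were rounded before fitting. The table has 60483 Ensembl genes, of which 21920 had 0 counts in all libraries. Gene symbols, types and positions came from GENCODE release 29, in which 56753 identifiers were found without regard to their version and 37168 with the same version, and 0.98% of the counts lay in identifiers without a name.

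Library totals ran from 18793041 to 41326638 expected counts. Genes were kept by filterByExpr with a minimum count of 10, which left 20235, and libraries were scaled by TMM. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with the Benjamini-Hochberg adjusted p under 0.05 as the threshold and no minimum fold. The standard error is the size of the log2 fold change divided by the square root of F. A fit with siRNA (3 levels) and cell line as terms, with 4 residual degrees of freedom, gave the mean of both EPIC1 siRNAs against the control, each siRNA against the control, the siRNAs against each other, and the lines against each other. A fit of line by EPIC1 siRNA (either of them against the control), with 3 residual degrees of freedom, gave the effect in each line and its difference between lines. In that fit the libraries of both EPIC1 siRNAs of a line stand as samples of 1 group and the lone control is assumed to vary like the others. Differences between the EPIC1 siRNAs within a line therefore count as its residual spread. Cell line was used as the block because, after the mean of each siRNA group was taken off, libraries of the same line correlated across genes at 0.91 to 0.96 (9 pairs) and those of different lines and siRNAs at -0.71 to 0.09 (18 pairs). The labels do not say whether libraries came from separate cultures, so the p-values measure a spread between libraries that is in part between lines and may be in part technical.

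The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The rule named EPIC1, the 12 highest and 12 lowest called genes for the mean of both siRNAs with a mean of at least 1 CPM and the same sign in all 6 libraries with EPIC1 siRNA (TNFRSF11B met it only through rounding, with equal counts of 0 in 1 pair), and the 6 highest and 6 lowest for the difference of the siRNAs. It also named 6 each way per line, filled by smallest p where none passed, 10 each way for A2780cis against A2780, up to 4 members of smallest p per gene list, MYC, EZH2, CDKN1A, HLA-A, HLA-B, HLA-C and B2M, and the EPIC1 neighbours TBC1D22A, TAFA5 and CERK. Clone names were counted and not named, and sex-linked marker genes were left out of the naming. Examples of list members in comparisons of single siRNAs and of lines were chosen after their values were seen. The 21 lists hold 507 genes, of which 506 were matched. They cover MHC class I antigen presentation, MHC class II, the type I interferon response, nucleic acid sensing and interferon ligands, MYC targets, PRC2, S phase, G2/M phase, p53 targets, the integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, NF-kB and inflammatory cytokines, mesenchymal and extracellular matrix, epithelial, leukocyte markers, NRF2 with glutathione and platinum transport, immune checkpoint ligands, mitochondrially encoded genes, replication-dependent histones and the RNA interference machinery. Lists were tested with camera on the signed root of F, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists of a comparison.

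Levels of EPIC1 have exact 95% Poisson intervals, and its percentages of control have intervals from the exact (Clopper-Pearson) binomial interval of the split of counts between the libraries. A gene with 0 counts in a group was set to a floor of 3 counts over the group, and its fold is given as a bound. Genes with 1 to 3 counts have a ratio with its counting interval, and no fold is given where both groups lie at or under the floor. These intervals and floors cover counting error only. Log2 values per library used an added count of 2.

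The procedure was tested on simulated data with changes added to 200 genes. For the mean of both siRNAs it recovered 13.4% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 83.3% of those changed 4-fold. In counts these were 9, 42 and 55 genes, and 23 unchanged genes were called besides. Of genes changed 2-fold it recovered 44.8% for siEPIC1_1, 44.8% for siEPIC1_2 and 40.3% for the difference of the siRNAs. For the lines it recovered 32.8% of them and within A2780cis, simulated without a difference between the EPIC1 siRNAs, 14.9%. Unchanged genes called in these comparisons were 14, 15, 9, 9 and 4, in the same order. In each comparison they made up a larger share of the calls than the adjusted threshold allows, so the threshold was too liberal in this simulation. The correlation and covariance of the siRNAs, and the overlap of lists of the real sizes, were compared with 20 simulations of a shared control without an effect; the overlap at matched sizes was added after the data were seen.

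The alternatives were DESeq2 size factors in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a filter of at least 5 CPM in 3 libraries, each library left out in turn, each line left out, both siRNAs coded as 1 level, no term for cell line, only the 6 libraries compared, and an estimated correlation for the lists. Counting only genes whose 3′ UTR lacks the 7-base words linked to the siRNAs was added after the data were seen. Alternatives of a pseudocount apply to normalised values and were not run on counts. Comparisons of 3 against 3 libraries have 10 splits, which did not keep libraries paired by line or siRNA. For the mean of both siRNAs 100 of 108 splits within lines were drawn. For the 3′ UTR search, 14651 tested genes with an annotated 3′ UTR were divided at random into 7325 and 7326. Genes were ranked by each siRNA against the mean of the other 2. The 7-base word of the strongest shift was picked in the first part and tested in the other by Fisher's exact test, and by logistic regression with 3′ UTR length and GC content. The siRNA sequences are not given with the data. Other computations used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.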

Results

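RNA was sequenced from 3 human cancer cell lines, each transfected with 3 siRNAs, which gave 9 libraries. A2780 is an ovarian cancer line, A2780cis is its cisplatin-resistant relative, kept in medium with 1 µM cisplatin, and Hs578T is a breast cancer line. The control siRNA, siLuc, targets luciferase, and siEPIC1_1 and siEPIC1_2 target EPIC1, a long intergenic non-coding RNA. Each siRNA was used at 40 nM and RNA was taken after 72 hours. Every combination of line and siRNA had 1 library, so the 3 libraries of a siRNA came from 3 different lines and there were no repeat cultures within a line. The control libraries held 36914482, 36977375 and 41326638 expected counts in A2780, A2780cis and Hs578T. With siEPIC1_1 the totals were 32345090, 30723612 and 35332574 in the same order, and with siEPIC1_2 they were 32033915, 18793041 and 35150336. Changes are log2 fold changes ± standard error from edgeR, with the adjusted p over 20235 genes.

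The first comparison asked how far each siRNA lowered its target. EPIC1 (ENSG00000224271.4, GRCh38 chromosome 22, 47631674 to 47855600, plus strand) was read at about 4 CPM (counts scaled to library size) with the control in A2780cis and Hs578T and was barely read in A2780. In A2780cis the normalised level was 3.88 CPM with the control (95% Poisson interval 3.28 to 4.55), 0.888 with siEPIC1_1 (0.59 to 1.28) and 2.6 with siEPIC1_2 (1.93 to 3.42). In Hs578T it was 3.63 with the control (3.07 to 4.26), 1.15 with siEPIC1_1 (0.835 to 1.55) and 2.74 with siEPIC1_2 (2.19 to 3.39). With siEPIC1_1 this left 22.9% of the control level in A2780cis (14.7 to 34.5%) and 31.7% in Hs578T (22.1 to 45%). With siEPIC1_2 it left 67% in A2780cis (47.6 to 92.9%) and 75.5% in Hs578T (57.2 to 99.4%). In A2780 the libraries held 2, 1 and 4 EPIC1 counts with the control, siEPIC1_1 and siEPIC1_2, so a loss of EPIC1 was not detectable there at this depth. Across the 3 lines the change was -1.79 ± 0.34 with siEPIC1_1 (adjusted p = 0.0439) and -0.34 ± 0.32 with siEPIC1_2 (adjusted p = 0.546). The mean over both siRNAs was -1.07 ± 0.27 (adjusted p = 0.0666), which passed the threshold in edgeR without a filter on low counts (adjusted p = 0.0103, range over the settings that gave a value 0.0103 to 1). DESeq2 gave it no adjusted p (log2 change -1.02, unadjusted p = 0.00888), and the stricter filter left EPIC1 out. EPIC1 was higher with siEPIC1_2 than with siEPIC1_1 by 1.45 ± 0.35 (adjusted p = 0.0366). The intervals cover counting error only, not the spread between cultures. Of the genes beside EPIC1, TAFA5, which encodes a secreted chemokine-like protein (chromosome 22, 48489460 to 48850912), rose by 2.06 ± 0.45 (adjusted p = 0.0396, higher in 5 of 6 libraries with EPIC1 siRNA). That call was lost with both siRNAs coded as 1 level (adjusted p = 0.24), without the control library of A2780cis (0.346) or Hs578T (0.137), without the siEPIC1_1 library of A2780 (0.0629) or A2780cis (0.122), and without the siEPIC1_2 library of A2780 (0.0529) or A2780cis (0.0724), against a range of 1.82e-06 to 1 over all settings. The 3′ UTR of TAFA5 carries GTACTAA, a 7-base word that was frequent among genes that rose with the mean of both siRNAs. TBC1D22A (0.03 ± 0.17), CERK (0.14 ± 0.14) and LINC00898 (-0.44 ± 0.55, chosen after its values were seen) did not pass the test.

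**Figure D1:**
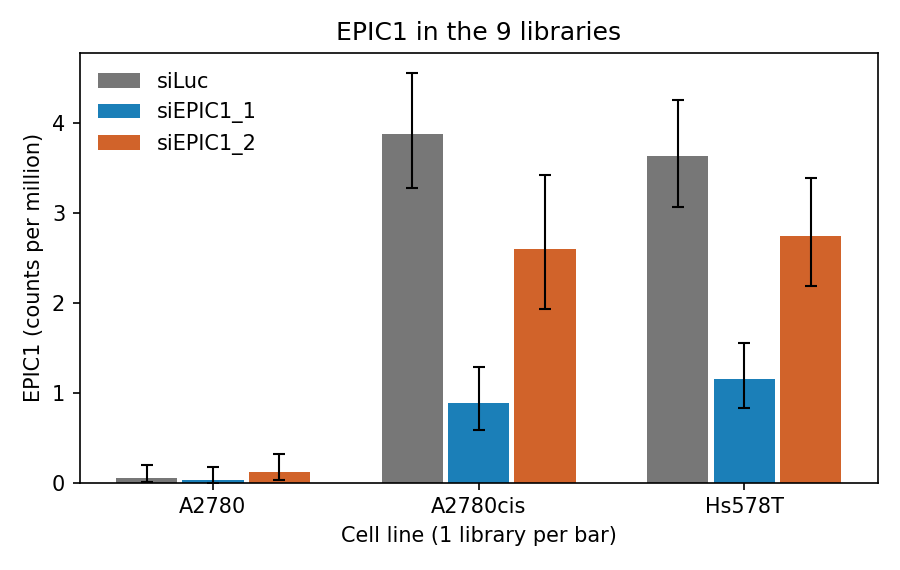
EPIC1 in CPM (vertical axis) in each of the 9 libraries, grouped by cell line and coloured by siRNA; each bar is 1 library and the error bars are 95% Poisson intervals. In A2780cis and Hs578T the siEPIC1_1 bars (0.888 and 1.15) lie below the siEPIC1_2 bars (2.6 and 2.74), and in A2780 all 3 bars are near 0.

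The main comparison asked which transcripts changed with EPIC1 siRNA, as the mean of both siRNAs against the control siRNA over the 3 lines. ITGA6, an integrin subunit that binds laminin (ENSG00000091409, chromosome 2, 172427354 to 172506282), rose by 2.70 ± 0.22, which is 6.51-fold (adjusted p = 0.00162). YES1, a kinase of the SRC family (ENSG00000176105, chromosome 18, 721588 to 812546), rose by 2.44 ± 0.17, which is 5.43-fold (adjusted p = 0.00162). PGAM1, a glycolytic enzyme, rose by 2.07 ± 0.16 (adjusted p = 0.00162), and RAB29, a small GTPase of vesicle traffic, rose by 2.07 ± 0.19 (adjusted p = 0.00212). ANXA5, a phospholipid-binding protein, rose by 2.12 ± 0.23, and CD274, which encodes the immune checkpoint ligand PD-L1, rose by 1.83 ± 0.34 (adjusted p = 0.0229). The other genes named as most increased were TNFRSF11B (2.28 ± 0.27), the metalloprotease ADAM12 (2.27 ± 0.34), C17orf58 (2.12 ± 0.20), MYPN (1.97 ± 0.40), the lncRNA APCDD1L-DT (1.91 ± 0.36) and MYEOV (1.81 ± 0.42). GTACTAA stood in the 3′ UTR of ITGA6, YES1, PGAM1, RAB29, ANXA5, TNFRSF11B, ADAM12 and C17orf58. It did not stand in that of CD274, MYPN or MYEOV, and APCDD1L-DT has no annotated 3′ UTR.

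Among the genes that fell were LSM11, a component of the U7 particle that processes histone mRNA (-1.53 ± 0.12, adjusted p = 0.00162), and CDK19, a kinase of the Mediator complex (-1.53 ± 0.17, adjusted p = 0.00395). The prefoldin subunit VBP1 fell by 1.72 on the log2 scale (SE 0.20), and the kinase gene NIM1K fell by 2.03 (SE 0.29). PAIP2B (-1.96 ± 0.28), DYNLT2B (-1.57 ± 0.19), NUDT11 (-1.47 ± 0.18), ARHGAP6 (-1.47 ± 0.32), the potassium channel gene KCNJ4 (-1.41 ± 0.26), TMEM87B (-1.41 ± 0.23) and STMN3 (-1.39 ± 0.30) fell as well. SFT2D3 was lowest in the ranking because it had 0 counts in the 3 siEPIC1_2 libraries against 536 in the 3 controls, which is at least 128-fold lower against a floor of 3 counts over the group. Its change with siEPIC1_1 was -1.29 ± 0.37 and did not pass the test (adjusted p = 0.186). TCTTTGA and GCTGAAA were the words most linked to lower levels with siEPIC1_1 and siEPIC1_2. LSM11, CDK19, NUDT11 and TMEM87B carry both in their 3′ UTRs, DYNLT2B carries the first and VBP1 the second. Of the 12 named genes that rose, ADAM12 carries both, ANXA5 the first and MYPN the second. The naming rule required the same sign in all 6 libraries with EPIC1 siRNA, so the shared sign of these 24 genes was fixed by selection. With equal counts set aside, 11 of the 12 named higher genes and all 12 named lower ones meet it. Of the 6 libraries, 2 are from A2780, where no loss of EPIC1 was seen. TNFRSF11B had 0 counts in A2780 with the control and with siEPIC1_2, so it has no sign in that library. For 5 of the 24 both groups of 1 line were at or under the floor of 3 counts, so the sign there is not informative. The summed counts with EPIC1 siRNA against the control count were 2 against 0 for TNFRSF11B in A2780, 2 against 1 for ADAM12 and 1 against 3 for ARHGAP6 in A2780cis, and 0 against 1 for NUDT11 and 1 against 3 for KCNJ4 in Hs578T. Counts were also low in A2780 and A2780cis for MYPN (10 against 4 and 12 against 4) and APCDD1L-DT (17 against 2 and 17 against 1). The 7 genes chosen beforehand without regard to their p did not pass the test: MYC changed by 0.04 ± 0.25, CDKN1A by 0.44 ± 0.22, EZH2 by -0.55 ± 0.17, HLA-A by 0.40 ± 0.38, HLA-B by -0.05 ± 0.16, HLA-C by 0.05 ± 0.16 and B2M by -0.13 ± 0.17.

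In all, 726 genes passed the test, 307 higher and 419 lower, and 4012 had an unadjusted p under 0.05. Of the 307, 272 were higher by more than 0.001 (log2) in all 6 libraries with EPIC1 siRNA than in the control of the same line, and of the 419, 300 were lower by more than 0.001 in all 6. Of the 15019 protein-coding genes tested, 282 rose and 406 fell, and of the 3108 long non-coding genes, 17 rose and 7 fell. The count dropped when the control library of A2780 (186 genes), A2780cis (38) or Hs578T (175) was left out, when the siEPIC1_1 library of A2780 (272) or A2780cis (260) or the siEPIC1_2 library of A2780cis (338) was left out, and to 0 without the line A2780cis (edgeR, at the adjusted threshold). The count was also 38 with both siRNAs as 1 level and 16 without the line A2780, and it rose to 1518 without Hs578T. The 8 named genes ITGA6, YES1, C17orf58, ANXA5, PGAM1, RAB29, SFT2D3 and LSM11 kept their call whichever single library was left out. The other 16 lost it without the control library of A2780cis. With both siRNAs as 1 level 15 of the 24 lost their call, and all 24 did without the line A2780cis.

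**Figure D2:**
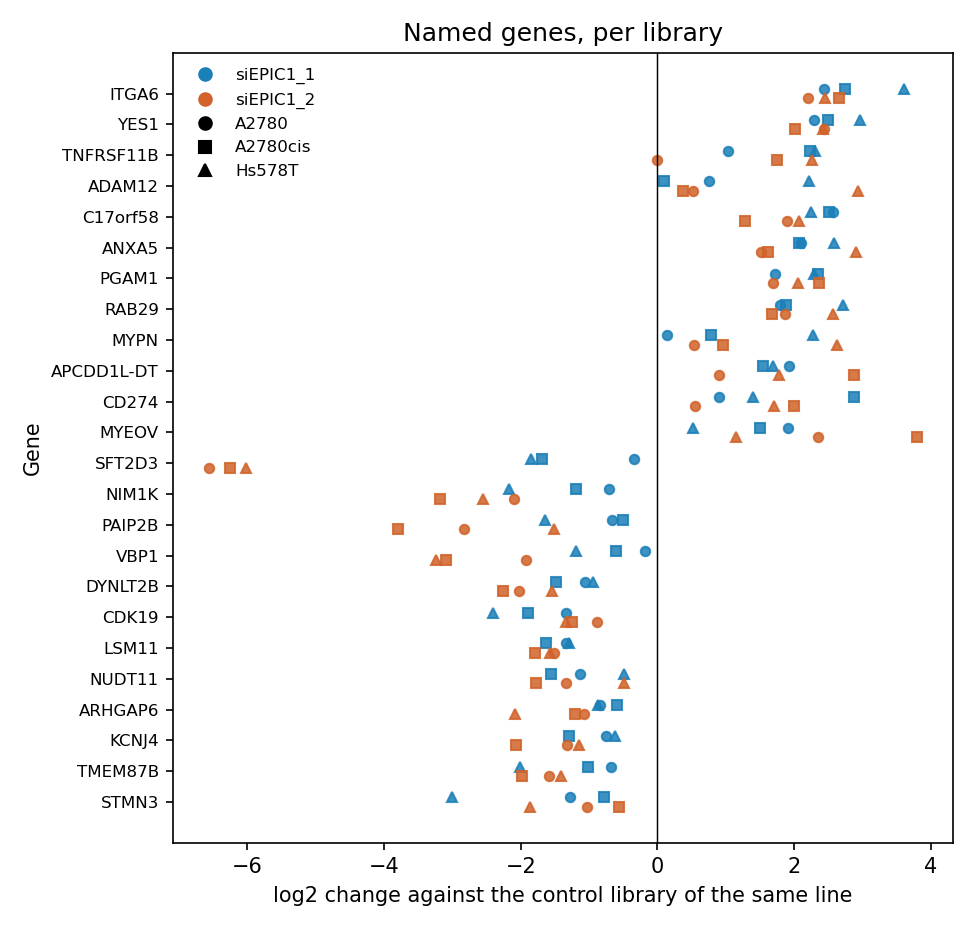
Log2 change against the control library of the same line (horizontal axis) of the 24 named genes (vertical axis), with 1 point per library with EPIC1 siRNA, coloured by siRNA and shaped by cell line. The 12 genes at the top are above 0, except TNFRSF11B at 0 with siEPIC1_2 in A2780. The 12 at the bottom are below 0 in all 6 libraries. The same sign in all 6 was a condition for naming a gene. The siEPIC1_2 points of SFT2D3 (0 counts) depend on the count of 2 added before the log. So do the points of TNFRSF11B in A2780, ADAM12 and ARHGAP6 in A2780cis and NUDT11 and KCNJ4 in Hs578T (3 counts or fewer).

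Of the 21 gene lists, genes of cell division had the lowest medians. Of 42 S phase genes tested, 5 fell. Among them were CDC45 (-1.15 ± 0.23), the ribonucleotide reductase subunit RRM1 (-0.83 ± 0.17), FEN1 (-0.78 ± 0.17) and MSH2 (-0.65 ± 0.14). The last was RAD51AP1 (-0.98 ± 0.22, named after its values were seen). Adjusted over the list alone, 15 S phase genes fell. The list's median was -0.64 (camera adjusted p = 4.55e-11 with a preset correlation, adjusted p = 0.641 with an estimated correlation). Of 51 G2/M genes, HMMR (-1.07 ± 0.19), the mitotic checkpoint kinase BUB1 (-1.03 ± 0.19) and ANP32E (-0.71 ± 0.13) fell and G2E3 (0.64 ± 0.13), whose 3′ UTR carries GTACTAA, rose. Adjusted over the list alone, 15 fell and 1 rose, with a median of -0.53 (adjusted p = 9.68e-09, and adjusted p = 0.656 with an estimated correlation). The G2/M median was -0.54 in A2780, -1.1 in A2780cis and 0.05 in Hs578T, where 31 of 51 were above 0. Of 23 cholesterol synthesis genes, DHCR24 (-1.25 ± 0.19), which encodes a late enzyme of the pathway and carries GCTGAAA, and ACAT2 (-0.72 ± 0.14) fell, also adjusted over the list alone, and the median was -0.29 (adjusted p = 0.00589, and adjusted p = 0.641 with an estimated correlation). For the 13 replication-dependent histone genes the median was -0.29 (adjusted p = 0.00589, and adjusted p = 0.746 with an estimated correlation), and 3 fell adjusted over the list alone. The 23 hypoxia and glycolysis genes had a median of -0.22 (adjusted p = 0.0256, and adjusted p = 0.776 with an estimated correlation), with medians of -0.05 in A2780, -0.05 in A2780cis and -0.53 in Hs578T. That call rests on Hs578T: it was lost without its control (adjusted p = 0.971), siEPIC1_1 (0.1) or siEPIC1_2 library (0.109), and the direction turned without the line (0.891). The stricter filter also ended it (0.119). The cholesterol call was lost without the control library of Hs578T (adjusted p = 0.0652) or that line (0.0921). The histone call was lost without the control library of A2780cis (adjusted p = 0.281), without that line (0.375) and with both siRNAs as 1 level (0.0929).

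Another 4 lists were higher on balance with the preset correlation. Of 22 genes of NRF2, glutathione and platinum transport, 4 rose, namely OSGIN1 (1.36 ± 0.16), the thioredoxin reductase TXNRD1 (1.20 ± 0.21), the quinone reductase NQO1 (0.93 ± 0.18) and SRXN1 (0.69 ± 0.15). TXNRD1 and SRXN1 carry GCTGAAA in their 3′ UTR, and OSGIN1 and NQO1 lack it. Adjusted over the list alone 6 rose, and the median was 0.11 (adjusted p = 0.00288, and adjusted p = 0.497 with an estimated correlation). Of 19 genes of NF-kB and inflammatory cytokines, BIRC3, an inhibitor of apoptosis whose 3′ UTR carries GTACTAA (1.27 ± 0.25), and the NF-kB subunit RELB (0.76 ± 0.13) rose. The list's median was 0.68 (adjusted p = 0.00288, and adjusted p = 0.641 with an estimated correlation), and 3 rose adjusted over the list alone. Of 28 p53 targets, CCNG1 (0.74 ± 0.14), which carries GTACTAA, and ZMAT3 (0.62 ± 0.12), which does not, rose, also adjusted over the list alone, and the median was 0.14 (adjusted p = 0.0256, and adjusted p = 0.656 with an estimated correlation). Of 9 immune checkpoint ligands, CD274 and CEACAM1 (2.25 ± 0.48) rose, 3 rose adjusted over the list alone, and the median was 0.25 (adjusted p = 0.0256, and adjusted p = 0.641 with an estimated correlation). In Hs578T CEACAM1 had 3 counts with EPIC1 siRNA and 3 with the control, at the floor, so its value rests on A2780 and A2780cis. The p53 call was lost without the control library of A2780 (adjusted p = 0.35) or A2780cis (0.056), without the siEPIC1_1 library of A2780 (0.0904) and without that line (0.289). The checkpoint ligand call was lost without the control library of A2780 (adjusted p = 0.0651) or A2780cis (0.056) and with the stricter filter (0.16). These 9 lists passed with the preset correlation and none of the 21 did with an estimated one, where the smallest adjusted p was 0.497.

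The other 12 lists did not pass. By edgeR, 0 of 21 genes of MHC class I antigen presentation (list median 0.13, adjusted p = 0.128), 0 of 8 of MHC class II (0.01, adjusted p = 0.789), 0 of 50 of the type I interferon response (0.12, adjusted p = 0.24) and 0 of 11 of nucleic acid sensing and interferon ligands (-0.11, adjusted p = 0.91) were called. Of 55 MYC targets EXOSC5 fell (-0.77 ± 0.17), 4 fell adjusted over the list alone, and the median was -0.08 (adjusted p = 0.23). Of 11 PRC2 genes none was called over all genes, 4 fell adjusted over the list alone, and the median was -0.23 (adjusted p = 0.108). Of 24 genes of the integrated stress and unfolded protein response, the cystine transporter SLC7A11, which carries all 3 words, rose (1.13 ± 0.14), with a list median of 0.01 (adjusted p = 0.431). Of 28 mesenchymal and extracellular matrix genes, COL6A1 rose (0.95 ± 0.19) and COL5A2 fell (-0.88 ± 0.17), with a median of 0.18 (adjusted p = 0.235). Of 12 genes of the RNA interference machinery, AGO1, which carries TCTTTGA, fell (-0.52 ± 0.11), with a median of 0.18 (adjusted p = 0.337). The 10 epithelial genes (0.5, adjusted p = 0.295), the 5 leukocyte markers (0.4, adjusted p = 0.26) and the 13 mitochondrially encoded genes (-0.18, adjusted p = 0.404) had no called member over all genes. Of the 25 called list members that the rule named, 22 lost their call without the control library of A2780, 22 without that of A2780cis, 19 without that of Hs578T, 17 and 18 without the siEPIC1_1 library of A2780 and A2780cis, and 15 without the siEPIC1_2 library of A2780cis. OSGIN1 was the 1 member that kept its call whichever library was left out. All 25, OSGIN1 included, lost their call without the line A2780 and without A2780cis, and 23 lost it with both siRNAs as 1 level.

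**Figure D3:**
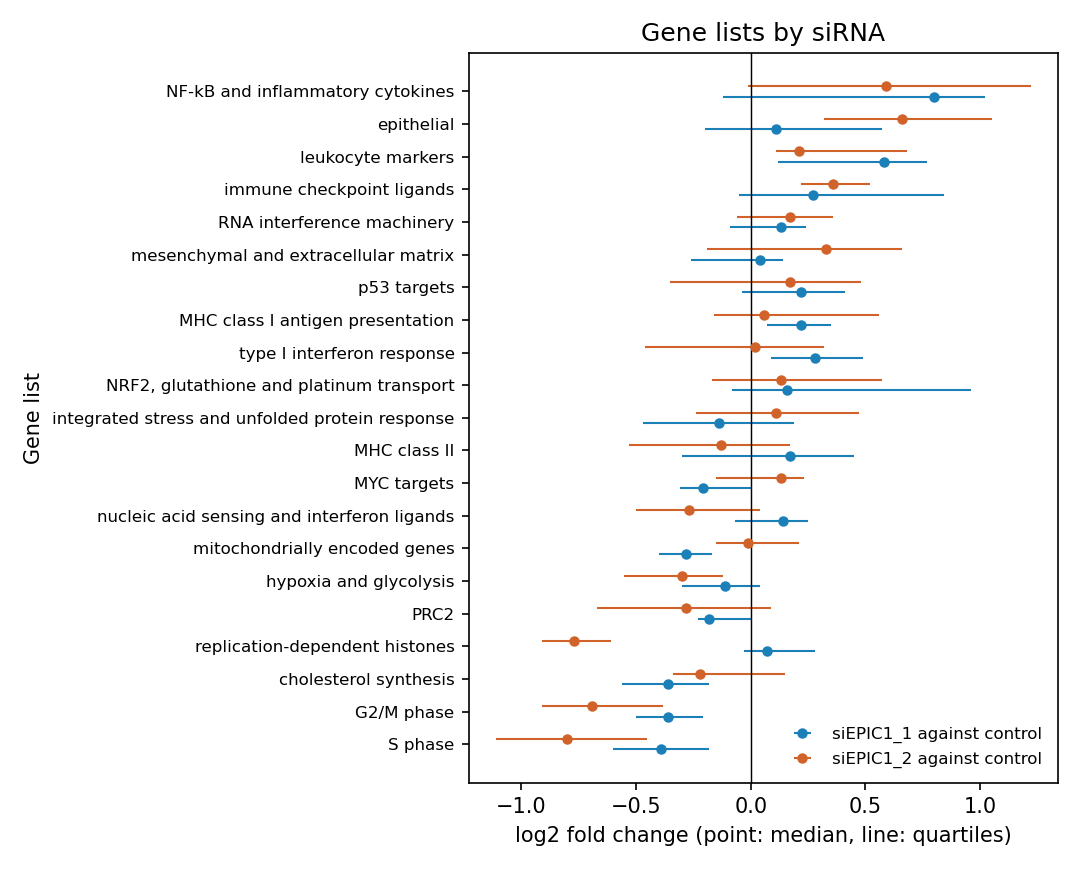
Log2 fold change against the control siRNA (horizontal axis) for the tested members of the 21 gene lists (vertical axis), separately for siEPIC1_1 and siEPIC1_2; points are list medians and lines run from the lower to the upper quartile of the genes. S phase genes have medians of -0.39 and -0.8 with siEPIC1_1 and siEPIC1_2, and replication-dependent histones have medians of 0.07 and -0.77.

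Each EPIC1 siRNA was then compared with the control by itself, since a change with 1 siRNA alone need not follow from its target. With siEPIC1_1 220 genes passed, 135 higher and 85 lower, and with siEPIC1_2 2053 passed, 752 higher and 1301 lower. The ribosomal protein gene RPL3 (chromosome 22, 39312882 to 39320389, mean level 1380 CPM) fell by 2.76 (SE 0.33, adjusted p = 0.00737) with siEPIC1_1 and changed by 0.11 ± 0.30 with siEPIC1_2. DNMT1, the maintenance DNA methyltransferase (chromosome 19, 10133345 to 10231286), changed by -3.45 ± 0.21 with siEPIC1_2, which is 10.9-fold lower (adjusted p = 0.000426), and by -0.36 ± 0.19 with siEPIC1_1 (adjusted p = 0.477). GLS, which encodes glutaminase, changed by -2.83 ± 0.19 with siEPIC1_2 (adjusted p = 0.000426) and by -0.12 ± 0.18 with siEPIC1_1 (adjusted p = 0.831). These falls were also seen in A2780, where EPIC1 was barely read, with 1 library per siRNA. There DNMT1 had 343 counts with siEPIC1_2 against 4590 with the control, and GLS had 501 against 3206. RPL3 had 17090 counts there with siEPIC1_1 against 96889 with the control. With siEPIC1_2, 12 of 42 S phase genes fell, such as CDC45 (-1.73 ± 0.28) and RRM2 (-1.22 ± 0.28), and 21 fell adjusted over the list alone. The S phase list's median was -0.8 with siEPIC1_2 (adjusted p = 4.04e-09, and adjusted p = 0.799 with an estimated correlation). With siEPIC1_1, RRM1 fell (-1.07 ± 0.20) as the single S phase gene called, and the median was -0.39 (adjusted p = 4.72e-06, and adjusted p = 0.726 with an estimated correlation). Of 51 G2/M genes, 13 fell and G2E3 rose with siEPIC1_2, and ANP32E fell with siEPIC1_1. Other lists passed with the preset correlation for siEPIC1_1 that did not for the mean of both siRNAs. These were the type I interferon response (median 0.28, adjusted p = 0.00285, and adjusted p = 0.728 with an estimated correlation), MHC class I antigen presentation (0.22, adjusted p = 0.0402, and 0.728 estimated) and MYC targets (-0.21, adjusted p = 0.000406, and 0.656 estimated), and no member of the 3 was called. The G2/M (-0.36, adjusted p = 0.000158), p53 (0.22, adjusted p = 0.00862), cholesterol (-0.36, adjusted p = 0.000253), NF-kB (0.8, adjusted p = 0.000375), NRF2 (0.16, adjusted p = 0.000187) and checkpoint ligand (0.27, adjusted p = 0.0391) lists also passed with siEPIC1_1. With siEPIC1_2 the G2/M (-0.69, adjusted p = 9.18e-08), histone (-0.77, adjusted p = 1.04e-06) and hypoxia and glycolysis (-0.3, adjusted p = 0.0399) lists passed besides S phase. With an estimated correlation none of the 21 lists passed for either siRNA, where the smallest adjusted p was 0.277 and 0.799. In the PRC2 list, SUZ12 (-0.84 ± 0.15), which carries GCTGAAA, and EED (-0.80 ± 0.15), which does not, fell and JARID2 (0.53 ± 0.13) rose with siEPIC1_2, while HMOX1, the haem oxygenase of the NRF2 list, rose with siEPIC1_1 (2.23 ± 0.40).

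Both siRNAs called 97 genes higher and 18 lower, and 3 were called in opposite directions. Both share the same control libraries, so the overlap was set against 20 simulations without any siRNA effect. In these the genes of smallest p in each direction were taken as lists of the real sizes. The lists shared 63 higher (56 to 76) and 39.3 lower genes (31 to 46). The 97 lay above the simulated range and the 18 below it. The simulations held no effect of either siRNA alone, while 1563 genes differed between the siRNAs in the data. This comparison therefore cannot tell how much of the overlap comes from the shared control, and no conclusion is drawn from it. Across genes, which are not independent replicates, the correlation of the changes of both siRNAs was 0.434, and the shared control alone gave 0.477 (0.458 to 0.496) in the simulations, while the covariance was 0.102 against 0.048 (0.0459 to 0.0508). Leaving out a library moved the siEPIC1_1 count to 77, 24 and 92 without its own A2780, A2780cis and Hs578T libraries, 59, 32 and 70 without the control libraries in that order, and 143 and 358 without the siEPIC1_2 libraries of A2780 and Hs578T. It moved the siEPIC1_2 count to 1260 and 632 without its A2780 and A2780cis libraries and to 916, 453 and 1266 without the control libraries of A2780, A2780cis and Hs578T.

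The direct comparison of siEPIC1_2 with siEPIC1_1 tested the difference between them and called 1563 genes, 616 higher and 947 lower with siEPIC1_2. DNMT1 (-3.09 ± 0.21, adjusted p = 0.00054) and GLS (-2.71 ± 0.19, adjusted p = 0.00054) were lower with siEPIC1_2, as were the transcription factor gene KLF15 (-2.61 ± 0.37) and the immune receptor-like gene FCRLA (-3.18 ± 0.65). FCRLA had 3 counts or fewer per library in A2780 and A2780cis, so its value rests on Hs578T (30 counts with siEPIC1_2 against 319). SFT2D3 had 0 counts with siEPIC1_2 against 222 with siEPIC1_1 (at least 60.8-fold lower), and the readthrough gene PEDS1-UBE2V1 had 0 against 308 (at least 84.4-fold lower). Higher with siEPIC1_2 were MAL, a membrane protein of lipid rafts (5.55 ± 0.54, adjusted p = 0.00278), RPL3 (2.88 ± 0.33, adjusted p = 0.00251) and its pseudogene RPL3P4 (3.20 ± 0.49), PSG5 (3.01 ± 0.51), the keratin gene KRT34 (2.89 ± 0.64) and LINC02957 (2.88 ± 0.61). The last 3 also had 3 counts or fewer per library in A2780 and A2780cis and rest on 1 library per siRNA of Hs578T, with 2629 counts against 358, 352 against 40 and 211 against 33. MAL had 0 counts in all 3 Hs578T libraries. Of the 13 replication-dependent histone genes, 9 were lower with siEPIC1_2, among them H3C10 (-1.47 ± 0.35), H2BC8 (-1.21 ± 0.26) and H4C8 (-1.16 ± 0.25), and all 13 were lower adjusted over the list alone. The histone median was -1.01 (adjusted p = 6.55e-09, and adjusted p = 0.906 with an estimated correlation). The type I interferon response (-0.29, adjusted p = 0.0287), S phase (-0.34, adjusted p = 0.0235) and G2/M (-0.35, adjusted p = 0.0235) lists were lower and MYC targets higher (0.21, adjusted p = 0.00948) with siEPIC1_2 than with siEPIC1_1, and none of the 21 lists passed with an estimated correlation (adjusted p = 0.906 or more). Of the 419 genes lower with the mean of both siRNAs, 202 were also called further down with siEPIC1_2 than with siEPIC1_1 and 18 further down with siEPIC1_1, while EPIC1 itself was higher with siEPIC1_2. The count of 1563 became 586, 281 and 958 without the siEPIC1_1 library of A2780, A2780cis and Hs578T, 937 and 405 without the siEPIC1_2 library of A2780 and A2780cis, and 1013 without the control library of A2780cis. PSG5 changed sign without the siEPIC1_1 library of Hs578T (-1.144) and lost its call without its siEPIC1_2 library (adjusted p = 0.666) and with DESeq2 (0.869). FCRLA lost its call without the siEPIC1_1 library of A2780 (adjusted p = 0.0502), A2780cis (0.0698) or Hs578T (0.0787) and without the siEPIC1_2 library of Hs578T (0.602). KRT34 lost it without the siEPIC1_1 library of A2780 (adjusted p = 0.0651), A2780cis (0.0503) or Hs578T (0.808), without the siEPIC1_2 library of A2780cis (0.0533) or Hs578T (0.732), without the control library of A2780cis (0.0685) and with DESeq2 (0.12). LINC02957 kept its call without the control library of Hs578T and lost it without each of the other 8 libraries (0.0616 to 1). MAL (adjusted p = 0.0661 and 0.0608) and PEDS1-UBE2V1 (0.052 and 0.054) lost theirs without the siEPIC1_1 or the siEPIC1_2 library of A2780cis, while RPL3P4, RPL3, SFT2D3, DNMT1, GLS and KLF15 kept their call whichever library was left out.

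Within each line, the libraries of both EPIC1 siRNAs were taken as 2 samples against the lone control, which was assumed to vary like the other libraries. The residual spread of this fit is thus the difference between the EPIC1 siRNAs, which was itself called for 1563 genes over the lines. In A2780 EPIC1 had 5 counts over both siRNA libraries against 2 in the control (ratio 1.42, 0.233 to 14.9), so a change there is a change with EPIC1 siRNA, without a loss of EPIC1 shown. No gene passed the edgeR test in any line, so the values here are those of smallest p and miss the threshold. In A2780 (adjusted p = 1) RAB29 changed by 1.83 ± 0.33, YES1 by 2.37 ± 0.43, CPA4 by 2.59 ± 0.51, CTHRC1 by 2.83 ± 0.56, C1S by 1.80 ± 0.37, LSM11 by -1.43 ± 0.30, TBC1D30 by -1.46 ± 0.40, ANKRD13B by -1.0 ± 0.29, NUDT11 by -1.23 ± 0.34 and CARMIL3 by -1.65 ± 0.49. LRRC8E had 1 count in the A2780 control and 74 with EPIC1 siRNA, a ratio of 42.1 (counting interval 7.33 to 1690), and TMOD1 had 13 against 0, at least 7.61-fold lower. In A2780cis (adjusted p = 1) PGAM1 changed by 2.36 ± 0.37, F2RL1 by 2.54 ± 0.45, RAB29 by 1.79 ± 0.33, YES1 by 2.28 ± 0.43, BROX by 1.76 ± 0.33, MIR22HG by 2.59 ± 0.50, LNPK by -2.01 ± 0.33, LSM11 by -1.71 ± 0.30, NUDT11 by -1.67 ± 0.34, H2AC15 by -1.89 ± 0.43, C4orf46 by -1.34 ± 0.31 and NDC80 by -1.57 ± 0.38. In Hs578T (adjusted p = 0.57) RAB29 changed by 2.64 ± 0.34, BROX by 2.40 ± 0.34, KIF3B by 2.62 ± 0.40, YES1 by 2.72 ± 0.44, ADAM12 by 2.62 ± 0.43, ANXA5 by 2.74 ± 0.45, INMT by -4.82 ± 0.52, CDC42EP5 by -2.36 ± 0.37, CEMIP by -3.25 ± 0.53, SLC25A24 by -2.09 ± 0.36 and SYNGR3 by -2.53 ± 0.45. MAGED4 had 29 counts in the Hs578T control and 2 with EPIC1 siRNA, 24.2-fold lower (6.13 to 210).

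edgeR called 0 genes in A2780, 0 in A2780cis and 0 in Hs578T, where 440, 732 and 978 had an unadjusted p under 0.05, and DESeq2 called 19, 30 and 113. For the difference between lines in the effect of EPIC1 siRNA, edgeR called 0 genes with 299 at an unadjusted p under 0.05. Differences between the EPIC1 siRNAs count as spread in this fit, so 0 calls here and within the lines do not show that effects are absent. DESeq2 called 4, which were MYOF, MAGED4, F2RL1 and INO80B-WBP1, and edgeR without a filter on low counts called 4, which were KXD1-AS1, ENSG00000273275, INO80B-WBP1 and ENSG00000281007.1, all named after their values were seen.

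The comparison of A2780cis with A2780 set the cisplatin-resistant line against its parental line over the 3 siRNAs, and its cells also had cisplatin in the medium. Antigen presentation and matrix genes were lower in A2780cis. Of 21 genes of MHC class I antigen presentation 15 were lower, with B2M at -2.67 ± 0.21, TAP1, a peptide transporter subunit, at -2.79 ± 0.24, HLA-A at -2.38 ± 0.51, HLA-B at -1.79 ± 0.19 and HLA-C at -1.25 ± 0.19, and none was higher. The list's median was -1.32 (adjusted p = 0.000518, and adjusted p = 0.912 with an estimated correlation). Of 28 mesenchymal and extracellular matrix genes, 19 were lower, such as the transcription factor TWIST1 (-7.47 ± 0.23), the collagen COL6A3 (-9.51 ± 0.24) and N-cadherin CDH2 (-3.62 ± 0.20), and 3 were higher, with a median of -1.9 (adjusted p = 5.01e-11, and adjusted p = 0.912 with an estimated correlation). Of 50 type I interferon response genes, 26 were lower, such as STAT1 (-2.79 ± 0.22), and 8 were higher, such as HERC5 (2.11 ± 0.17), with a median of -1.02 (adjusted p = 0.0139, and adjusted p = 0.912 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, was higher by 1.14 ± 0.25, and MYC differed by 0.77 ± 0.28 and missed the threshold (adjusted p = 0.0508).

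The genes of largest difference were nearly absent from the other line. Higher in A2780cis were INHBA, a subunit of activin (11.87 ± 0.69), the macrophage elastase MMP12 (10.63 ± 0.34) and FILIP1 (10.62 ± 0.41). Against 0 counts in A2780, HMX1 was at least 624-fold higher, OPN5 at least 333-fold, TLR8-AS1 at least 282-fold, C1orf105 at least 261-fold and PALM2AKAP2 at least 212-fold. The fatty acid transporter gene CD36 had 2 counts in A2780 and a ratio of 11400 (3150 to 94000), and BACE2 had 1 count and a ratio of 3270 (586 to 129000). Against 0 counts in A2780cis, OTOA was at least 4350-fold lower, the homeobox gene DLX5 at least 2350-fold, FIGN at least 1230-fold, ESRRG at least 1220-fold, the developmental regulator PAX2 at least 1130-fold, GRIK1 at least 1060-fold and LAYN at least 758-fold. With 1 count in A2780cis, DLX6-AS1 was 34800-fold lower (6250 to 1380000), RGS1 14800-fold (2660 to 586000) and ZPLD1 12900-fold (2320 to 510000). In all, 8849 genes passed, 4272 higher and 4577 lower in A2780cis, and the 20 genes named here kept their call whichever library was left out. As a scale for the siRNA effects, Hs578T differed from A2780 in 14552 genes, 7222 higher and 7330 lower.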

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

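The tests of the loss of EPIC1 and of a stronger loss with siEPIC1_2 were chosen after related results had been seen. So was the test of the EPIC1 siRNA words among genes that fell with the mean of both siRNAs. The searches for 7-base words of the control siRNA and of siEPIC1_2 were chosen before. As background, a siRNA can silence transcripts whose 3′ UTR matches the short seed at its 5′ end, here searched as words of 7 bases.

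The 307 genes higher with the mean of both EPIC1 siRNAs over the 3 lines were the pattern weighed first. Of these, 97 passed with both siRNAs when each was tested alone. A loss of EPIC1 as the whole cause is argued against by A2780, where EPIC1 had 1 to 4 counts per library. The 200 genes of smallest p that were higher in the other lines had a median change of 0.774 there (0.723 to 0.822). Held out in A2780cis and Hs578T, the medians were 0.873 and 0.804. The interval comes from resampling the 200 genes, all set against 1 control library, and holds no error between libraries. A2780 and A2780cis are related lines. The word GTACTAA, picked in one part of the genes, stood in the 3′ UTR of 87 of 151 genes that rose in the other part (57.62%) and of 5.589% of the rest (odds ratio 22.96, Fisher exact p = 1.832e-64), and in 0 of 3 EPIC1 transcripts. ITGA6, YES1, TNFRSF11B, ADAM12, C17orf58, ANXA5, PGAM1, RAB29, TAFA5, CCNG1, BIRC3, G2E3 and SLC7A11 carry it, and CD274, OSGIN1, NQO1, RELB and CEACAM1 do not. Silencing of these genes by the control siRNA, so that they look higher with any other siRNA, is a candidate explanation that stays open, as do effects of EPIC1 on the genes without the word, and it was not checked against the siRNA's sequence.

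Genes lower with siEPIC1_2 than with siEPIC1_1 and the control were the next pattern. A stronger loss of EPIC1 with siEPIC1_2 is argued against by EPIC1 itself, which was higher with siEPIC1_2 than with siEPIC1_1 by 1.45 ± 0.35. The word GCTGAAA stood in 178 of 680 genes lower with siEPIC1_2 than with the mean of the other siRNAs (26.18%) and in 12.08% of the rest (odds ratio 2.58, Fisher exact p = 4.835e-21), and in 2 of 3 EPIC1 transcripts, as 12.3% of all words stand in some EPIC1 transcript. Off-target silencing by siEPIC1_2 may therefore account for part of these genes. Of the genes with a 3′ UTR called lower than with the control and with siEPIC1_1, 451 of 643 lack this word. Overlapping words were not counted. SUZ12, HSPD1 and DHCR24 carry the word, and EED, DNMT1 and GLS lack it in their 3′ UTR. HSPA5 carries it and rose with siEPIC1_2, and MAL and KRT34 carry it and were higher with siEPIC1_2 than with siEPIC1_1. Matches elsewhere in the transcripts of these genes were not searched.

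The last pattern was the 419 genes lower with the mean of both EPIC1 siRNAs, LSM11, CDK19 and the 5 called S phase genes among them. Of the 419, 18 passed with both siRNAs when each was tested alone, and 202 were called further down with siEPIC1_2 than with siEPIC1_1. The 200 genes of smallest p that were lower in the other lines had a median of -0.541 in A2780, where EPIC1 was barely read. The interval of -0.617 to -0.514 comes from resampling these genes and holds no error between libraries. Held out in A2780cis and Hs578T, the medians were -0.845 and -0.585, so A2780 argues against a loss of EPIC1 as the whole cause. Either EPIC1 siRNA word was more frequent among genes that fell than among the rest (odds ratio 2.091, Fisher exact p = 1.088e-06). The same held among genes that rose (1.945, Fisher exact p = 0.0001195). The model with 3′ UTR length and GC content was run after this was seen. Against genes not called, it gave an odds ratio of 1.975 (1.41 to 2.769) for genes that fell. For genes that rose it gave 1.238 (0.8479 to 1.809), and the intervals overlap. Seed matches of both siRNAs may thus contribute, and LSM11 and CDK19 carry both words. Of the 404 with a 3′ UTR that fell, 216 carry none of the picked words, the 5 called S phase genes among them. Overlapping words were not counted. Of the 216, 104 fell further with siEPIC1_2, which left more EPIC1, CDC45, FEN1 and HMMR among them, and 7 further with siEPIC1_1. For the 216 an effect of EPIC1 stays open, as do seed matches through overlapping words.

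For the mean of both siRNAs, 5 of 100 splits, the real one included, called as many genes as the real 726. The 4 others, with 919 to 2502 genes, all put siEPIC1_2 in the place of the control in all 3 lines. Each is thus itself a comparison of siRNAs, so this count cannot decide on chance and does not exclude it. It points to siEPIC1_2 libraries that stand apart. With siEPIC1_1 in that place in all 3 lines, 4 splits called 0 to 365. With the controls in place and the EPIC1 siRNAs exchanged in some lines, 3 splits called 5 to 18. The remaining 88 called 0 to 5. For siEPIC1_1 the real split called 220 genes, for siEPIC1_2 2053, for siEPIC1_2 against siEPIC1_1 1563, for A2780cis against A2780 8849 and for Hs578T against A2780 14552. The highest other split called 0 in each, the real one was 1 of 10, and 10 splits are too few for a share under 0.05. These splits also did not keep libraries paired by line or siRNA. For the lines, every other split puts libraries of both lines in the same group, so the line differences enter the spread. Their 0 calls were set by the design and say nothing on chance.

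In 12 gene lists the effect of EPIC1 siRNA differed between lines by camera with the preset correlation, and in none with an estimated correlation, where the adjusted p was 0.27 or more. Each line has 1 control library, and the preset correlation does not cover a shift of many genes in that library, so a difference between the lines is not shown. In A2780 no loss of EPIC1 was seen either. The values are medians of the difference in log2 effect. Epithelial genes differed by -2.05 between Hs578T and A2780cis (adjusted p = 0.00014), with medians of 0.91 in A2780, 0.74 in A2780cis and -0.85 in Hs578T; 5 of the 10 had 3 counts or fewer on a side in either line, and the other 5 differed by -2.12. G2/M genes differed by 1.08 between Hs578T and A2780cis (adjusted p = 1.2e-23), with medians of -0.54, -1.1 and 0.05 in the same order. S phase genes differed by 0.44 between the same lines (adjusted p = 0.00801), and MYC targets by 0.25 (adjusted p = 0.00645). Between Hs578T and A2780, mitochondrially encoded genes differed by 1.27 (adjusted p = 3.11e-18), type I interferon response genes by -0.69 (adjusted p = 3.26e-06), MHC class I genes by -0.69 (adjusted p = 5.87e-05), hypoxia and glycolysis genes by -0.72 (adjusted p = 2.07e-06), MHC class II genes by -1.73 (adjusted p = 0.00536; 5 of the 8 had 3 counts or fewer on a side, and the other 3 differed by -0.68) and p53 targets by -0.35 (adjusted p = 0.00399). Between A2780cis and A2780, replication-dependent histones differed by -0.66 (adjusted p = 0.000466) and genes of the integrated stress and unfolded protein response by -0.54 (adjusted p = 9.69e-05).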

How the results depend on the processing

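One alternative, counting only genes without any of the 7-base words, was chosen after the data were seen. Of the tests of single named genes under the alternatives, 2465 kept their side of the threshold, 386 no longer passed, 129 newly passed and 1 reversed. For gene lists the numbers were 303, 25, 26 and 1. A reversal was counted only where the gene or list passed in the main fit or in the alternative. For those that passed in neither, direction was not compared. DESeq2 size factors left every count of genes and lists within 1.5 times. For the mean of both siRNAs (726 genes) the count was 1707 with DESeq2, 2125 without a filter, 38 with both siRNAs as 1 level, 0 by edgeR without a term for cell line, 16 without A2780, 0 without A2780cis, 1518 without Hs578T and 216 among the 10323 genes with a 3′ UTR and without the words (65 higher, 151 lower, against 307 and 419); by construction this leaves out the 160 higher genes with the control siRNA's word, and 88 of the 307 have a 3′ UTR without any word. For siEPIC1_1 (220) it was 780 with DESeq2, 1070 without a filter, 0 without the line term and 21 without the words. For siEPIC1_2 (2053) it was 3190, 3281, 0 and 1120 in that order, and 1347 with the 6 libraries compared. For siEPIC1_2 against siEPIC1_1 (1563) it was 2858 with DESeq2, 2876 without a filter and 927 without the words. Within A2780, A2780cis and Hs578T DESeq2 called 19, 30 and 113 genes against 0 by edgeR, and without a filter 26 passed in Hs578T. For the difference between lines DESeq2 and the fit without a filter each called 4. Hs578T against A2780 gave 9392 with the stricter filter, which tests fewer genes. Of the 21 gene lists 9 passed, 0 with an estimated correlation and 16 without a filter. Apart from the smaller sets of genes, the cause was not tested.

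Leaving out each library in turn gave 38 to 1054 genes for the mean of both siRNAs, 24 to 358 for siEPIC1_1, 453 to 2428 for siEPIC1_2, 281 to 1641 between the siRNAs, 6319 to 9699 for A2780cis against A2780, 12915 to 14471 for Hs578T against A2780, 0 to 0 within each line and for the difference between lines, and 6 to 12 lists. A fit without a line's control gives no value for that line. The hypoxia and glycolysis list changed direction without Hs578T (adjusted p = 0.891), and PSG5 changed sign (-1.144) between the siRNAs without siEPIC1_1 replicate 3, its highest value being 3.16. In A2780 EPIC1 had 1 to 4 counts per library, so depth left a loss of EPIC1 undetectable there. For EPIC1 the mean of both siRNAs has no adjusted p from DESeq2 and no value with the stricter filter.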

Other observations

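Members of the stress response, MYC target and p53 lists moved with single siRNAs; the examples were chosen from the lists after their values were seen. The chaperone genes HSPA5 (1.56 ± 0.35) and SDF2L1 (1.53 ± 0.30) rose with siEPIC1_2, and HSPD1, a mitochondrial chaperonin, fell (-1.30 ± 0.19); HSPA5 and HSPD1 carry the word GCTGAAA in their 3′ UTR. In the p53 list, ZMAT3 (1.33 ± 0.14) and PLK3 (0.81 ± 0.18) were higher with siEPIC1_2 than with siEPIC1_1 and TP53I3 (-1.51 ± 0.23), FAS (-1.02 ± 0.26), XPC (-0.77 ± 0.16), TNFRSF10B (-0.75 ± 0.15) and BAX (-0.61 ± 0.13) were lower. FAS carries GCTGAAA and TCTTTGA, ZMAT3 carries TCTTTGA and XPC carries GTACTAA. PLK3, TP53I3, TNFRSF10B and BAX carry none of the picked words. In A2780cis against A2780, the glutamate-cystine exchanger SLC7A11 was higher (3.0 ± 0.16). Of the 22 genes of NRF2, glutathione and platinum transport, 5 were higher and 6 lower there, 14 were below 0 and the median was -0.25, while camera's direction was up (adjusted p = 0.638). Higher were the NRF2 targets OSGIN1 (3.38 ± 0.18) and SRXN1 (2.39 ± 0.18), the copper transporter gene ATP7A (1.15 ± 0.17) and the repair gene ERCC1 (1.44 ± 0.24), and lower were the copper transporter genes SLC31A1 (-0.71 ± 0.22) and ATP7B (-0.72 ± 0.18), XPA (-0.61 ± 0.21), GSTP1 (-0.56 ± 0.14) and GCLC (-0.55 ± 0.19).

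For siEPIC1_1, the word TCTTTGA stood in the 3′ UTR of 35 of 62 genes lower with siEPIC1_1 than with the mean of the other siRNAs (56.45%) and in 17.79% of the rest (odds ratio 5.992, Fisher exact p = 1.259e-11). The genes with the control siRNA's word GTACTAA had a higher median change than those without it in all 6 libraries with EPIC1 siRNA, by 0.202 to 0.402 on the log2 scale, A2780 included. RPL3 and DNMT1 carry none of the 3 words in their 3′ UTR. The transcripts of RN7SL1 and RN7SL2 took 4.943 to 6.973% of the counts and mitochondrially encoded genes 0.1459 to 0.5596%.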
